A study of Homo sapiens with 9 samples.

How the data were processed

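PANC1 cells were profiled by RNA sequencing in 9 libraries, 3 untreated controls, 3 with a NUSAP1 plasmid and 3 with an siRNA against NUSAP1. RNA was poly(A)-selected and libraries were made with a dUTP protocol, per the labels. Whether the counting used the strand is not given in the sources used here. The authors deposited one table with a read count and an FPKM value for each of 60612 genes in each library. Counts are the authors' deposited whole-number values per gene, and the deposited FPKM values (fragments per kilobase of transcript, scaled to the library) scale them by length and library size. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d. The settings of these tools and the genome build are not given in the sources used here. The table writes an FPKM of 0 as 0.0001, and 221 entries, each for 1 gene in 1 library, had this value beside a count above 0. All sample columns were used.

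The planned analysis was limma on log2(FPKM + 1), with edgeR in its place if the table held counts. As it did, edgeR 4.0.16 (R 4.3.3) with TMM factors and quasi-likelihood tests was used on the counts, and the limma fit (limma 3.58.1) was kept as an alternative. Genes with an FPKM of at least 1 in at least 3 of 9 libraries were tested (12545 genes). One model with 3 groups and 6 residual degrees of freedom gave 3 comparisons, overexpression with control, knockdown with control, and overexpression with knockdown. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. The common biological coefficient of variation was 0.226. Standard errors of log2 fold changes were taken as the size of the change over the square root of its F statistic and are approximate. NUSAP1, LDHA, HIF1A and MYC were also tested with exact two-sided permutation tests of mean log2(FPKM + 1).

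Total counts ranged from 57115172 to 73386227 per library. With no counts in a group, a floor of 3 counts over the group gave a lower bound of the fold change, which covers counting error only. Tested on simulated data with the means and spread of these libraries, edgeR found 11.9%, 58.2% and 97.0% of genes changed 1.5-, 2- and 4-fold after overexpression and 4.48%, 50.7% and 84.8% after knockdown. It made 10 and 6 false calls among 12345 unchanged genes. Between overexpression and knockdown it found 14.9%, 59.7% and 93.2%, with 7 false calls among 12145. In each comparison against control only 67, 67 and 66 genes were changed by these folds. Many more genes were called in the real data, where these shares may not hold.

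The comparisons, the filter, 21 gene lists and the rule for the genes named were fixed before the data were examined. The lists were study genes, glycolysis and lactate, hypoxia targets outside glycolysis, tricarboxylic acid cycle, nuclear-encoded respiratory chain, mitochondrially encoded, mitosis, DNA replication, mesenchymal and invasion, epithelial, interferon response, NF-kappaB and cytokines, p53 targets, unfolded protein and integrated stress response, heat shock, cholesterol synthesis, YAP and TEAD targets, immediate early, cytosolic ribosomal proteins, replication-dependent histones, and other cell types. Each was tested with camera (preset correlation 0.01) and adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Camera sets a list against the other genes, while fry asks only whether its members changed. Members were also adjusted over the list alone. GO and KEGG terms given in the table with 15 to 300 tested genes were tested the same way. A list of hepatocyte transcripts was added after the counts were seen.

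The rule for the genes named takes NUSAP1, LDHA, MYC and HIF1A, and the 8 genes with the largest increase and the 8 with the largest decrease among those that passed, whose groups did not overlap, with a mean FPKM of at least 5 in the higher group and no clone, antisense or pseudogene name. It also takes up to 2 members of each list with the smallest adjusted p, and 8 genes each with the largest changes in the same and in opposite directions in the comparisons against control. For overexpression against knockdown it takes the top 5 each way. Not all of these are named, and IFNB1, PDK1, HK2 and PFKM, and the further hepatocyte genes, were chosen after their values were seen. Some genes that the rule takes are not reported here. Genes with near-identical copies or processed pseudogenes, such as histones, NBPF and NPIPB genes, CD24, LDHA and ribosomal proteins, may share reads in ways the table does not show. The loci of NUSAP1, SREBF1, P4HA2, MIEF1, KIF20A, IFIT1, IFIT2, CD68, RPS3A, NOCT, TAF15 and ATP5F1B overlap another gene of the table. The gene identifiers were compared with GENCODE 29 on GRCh38, where 58394 of 60612 matched and 99.9% of those overlapped the deposited position.

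Whether replicate numbers pair libraries across groups was checked on deviations from the group means. Knockdown and control libraries of the same number correlated at 0.139, 0.132 and 0.117, overexpression and control at -0.0930, 0.000226 and 0.00168, and overexpression and knockdown at -0.0523, 0.251 and 0.0694. Numbers were therefore taken to pair knockdown with control only. The main fit does not use this pairing, and a fit with the number as a block is given as an alternative. The overlap of both comparisons against control was set beside 20 simulations of unchanged groups that share the control libraries. Heptamers in annotated 3′ UTRs of at least 50 bases were tested for their relation to the log2 fold changes by regression, against 100 shuffles of the fold changes over genes. This was checked on simulated data with 1 planted heptamer, which was found.

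Alternatives were limma on log2(FPKM + 1), a pseudocount of 0.1, no filter, a filter of FPKM 5, quantile normalization, FPKM rescaled to TPM, a median shift, RLE factors, library totals alone, DESeq2 1.42.0, robust empirical Bayes, NUSAP1 left out before TMM, fits on the compared groups only, the replicate block, a 2-fold minimum, and each library left out in turn. Of these, limma on log2(FPKM + 1) as an alternative, DESeq2, RLE factors, library totals and the fit without NUSAP1 were chosen after seeing the data, as were a block fit of control and knockdown alone and a fit without the 4 libraries with hepatocyte transcripts. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.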

Results

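RNA sequencing of 9 libraries from PANC1, a human pancreatic ductal adenocarcinoma cell line, was examined. The libraries fell into 3 groups of 3: untreated control cells, cells given a plasmid for flag-tagged NUSAP1 (overexpression) and cells given a small interfering RNA (siRNA) against NUSAP1 (knockdown). NUSAP1 encodes a microtubule-binding protein of the mitotic spindle. The series title links it to LDHA, the lactate dehydrogenase subunit that makes lactate from pyruvate, and to glycolysis. The total count per library was 73386227, 61990674 and 57115172 in control 1, 2 and 3, 62442203, 62799600 and 62774449 in overexpression 1, 2 and 3, and 57518565, 60667883 and 69764307 in knockdown 1, 2 and 3. The first principal component held 52.4% of the variance and set the overexpression libraries apart from the other 6, and the second held 12.9% and parted control from knockdown. No library received an empty plasmid or a control siRNA according to the labels, so each comparison against control includes the effect of transfection. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

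NUSAP1 (ENSG00000137804, chromosome 15, 41320794 to 41381050) was far higher in every overexpression library and lower in every knockdown library than in any control library. Its FPKM was 30.9, 34.0 and 42.1 in the control libraries, 13325, 13792 and 12910 in the overexpression libraries, and 12.004, 13.8 and 11.6 in the knockdown libraries. The group means were 35.7 ± 5.80 in control, 13342 ± 441 in overexpression and 12.5 ± 1.19 in knockdown (SD, n = 3 each). The log2 fold change was 8.63 ± 0.15 (SE) after overexpression (edgeR adjusted p = 1.31e-08), which is 396-fold, and -1.53 ± 0.11 after knockdown (adjusted p = 0.000162). NUSAP1 transcripts, including those from the plasmid, took 5.78%, 5.998% and 5.63% of all counts in the 3 overexpression libraries, against 0.0132%, 0.0145% and 0.0180% in the controls. The locus overlaps OIP5, whose reads can fall in the same positions.

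LDHA (ENSG00000134333, chromosome 11, 18394560 to 18408425) was lower in both perturbations, not only after knockdown. Its FPKM was 139, 148 and 155 in the control libraries, 77.2, 71.7 and 80.9 in the overexpression libraries, and 59.8, 58.5 and 69.9 in the knockdown libraries. The means were 147 ± 8.04, 76.6 ± 4.61 and 62.7 ± 6.21 (SD, n = 3 each). LDHA fell by 0.86 ± 0.10 (SE) on the log2 scale after overexpression (adjusted p = 0.000145) and had a log2 fold change of -1.24 ± 0.10 after knockdown (adjusted p = 0.000283). The annotated LDHA 3′ UTRs hold 3 positions of the heptamers that were more frequent in genes lower after knockdown, between bases 18407282 and 18407498. HIF1A, the oxygen-regulated subunit of a transcription factor of glycolysis genes, had a mean FPKM of 19.9 in control, 21.9 in overexpression and 13.7 in knockdown. Its log2 fold change was 0.22 ± 0.15 after overexpression (adjusted p = 0.246) and -0.56 ± 0.15 after knockdown (adjusted p = 0.0399). The latter no longer passed without control 1 (adjusted p = 0.0916), control 2 (0.103), control 3 (0.0648), knockdown 1 (0.0877) or knockdown 3 (0.0710). It did not pass with limma on the FPKM values (0.0542), with pseudocount 0.1 (0.0555), after quantile normalization (0.0541), in TPM (0.170), with library totals only (0.0613), without a filter (0.0672) or without the 4 libraries with hepatocyte transcripts (0.321). MYC, a growth-promoting transcription factor, varied within groups. Its FPKM was 36.0, 30.3 and 4.41 in the overexpression libraries and 12.5, 10.4 and 1.06 in the knockdown libraries, against 13.1, 12.3 and 12.7 in control. The log2 fold changes of MYC were 0.98 ± 0.87 (adjusted p = 0.375) and -0.71 ± 0.86 (adjusted p = 0.648). In exact two-sided permutation tests of 3 against 3 libraries, where 0.1 is the smallest p possible, p was 0.1 for NUSAP1 and LDHA in each comparison. The exact p was 0.5 for HIF1A and 0.7 for MYC after overexpression, and 0.1 and 0.2 after knockdown. These tests exchange libraries freely and do not keep the pairing of knockdown with control by number.

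**Figure D1:**
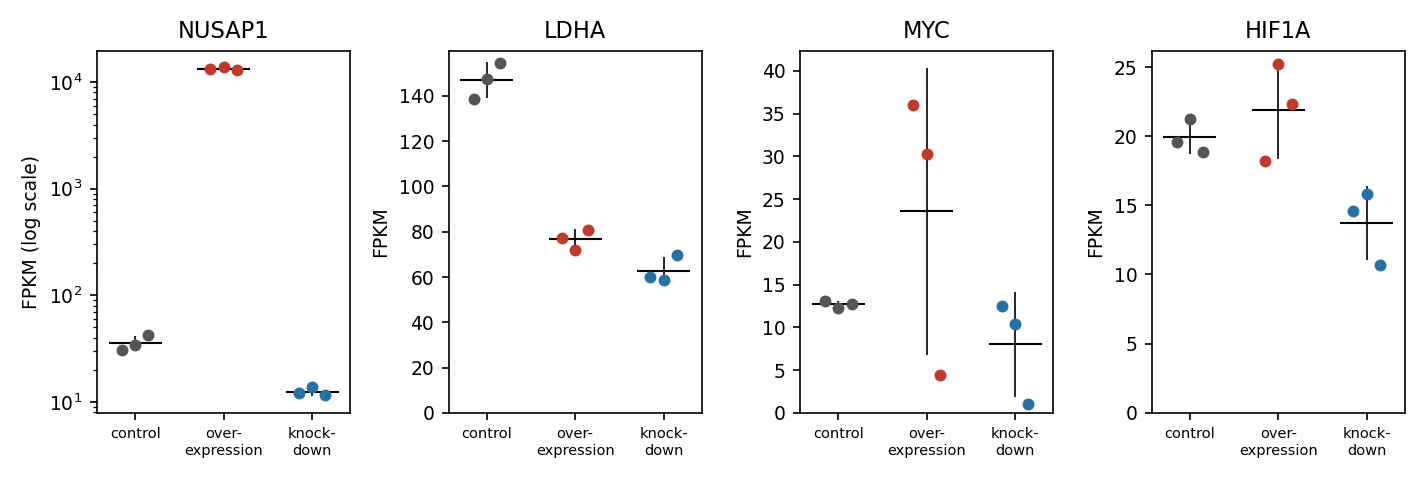
FPKM of NUSAP1 (log scale), LDHA, MYC and HIF1A (linear scales from 0) in each library (points) by group, with the group mean (horizontal line) and SD (vertical line). NUSAP1 is highest in the 3 overexpression libraries, LDHA is highest in the 3 control libraries, and MYC is low in overexpression 3 and knockdown 3.

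The comparison of overexpression with control asks what a large excess of NUSAP1 transcript does to expression. Genes of the interferon response, cytokine genes under NF-kappaB, immediate early genes and replication-dependent histone genes were several-fold higher in the overexpression libraries. Genes of cholesterol synthesis, glycolysis, the mitochondrial genome and DNA replication were lower. With an estimated correlation the last 3 of these lists did not pass (adjusted p = 0.290, 0.623 and 0.326). Of 12545 genes tested, 6702 changed, 3438 higher and 3264 lower, and 2233 of these had changed at least 2-fold (1304 higher and 929 lower). In TPM, where the median gene shifts by 0.14 in both comparisons against control, the 6222 genes that changed were 3974 higher and 2248 lower, while limma on the FPKM values gave 3020 higher and 3803 lower and a median shift 2924 higher and 3928 lower. With a filter of FPKM 5, which tests fewer genes, 4229 changed.

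Among the largest increases after overexpression, EGR1, an immediate early transcription factor, had a mean FPKM of 1.38 ± 0.116 in control and 96.6 ± 6.84 in overexpression (SD, n = 3 each), a log2 fold change of 6.21 ± 0.10 (SE, adjusted p = 1.31e-08). IFIT2, an interferon-induced inhibitor of translation whose locus overlaps LIPA, went from 0.238 ± 0.0524 to 47.4 ± 4.76, a log2 fold change of 7.71 ± 0.20 (adjusted p = 1.2e-07). ANKRD1, a target of YAP and TEAD, went from 0.346 to 38.2 (6.88 ± 0.58, adjusted p = 2.67e-05) and GADD45A, a stress-induced growth arrest gene, from 7.66 to 180.3 (4.64 ± 0.15, adjusted p = 2.43e-07). The chemokine gene CCL5 rose from 0.801 to 29.3 (5.26 ± 0.19), NOCT from 2.67 to 66.8 (4.72 ± 0.13, at a locus overlapping ELF2) and the type III interferon gene IFNL1 from 0.0387 to 19.6 (8.93 ± 0.60). Among the largest decreases, SCD, the desaturase that makes monounsaturated fatty acids, fell from 404 ± 11.2 to 79.1 ± 2.98, a log2 fold change of -2.27 ± 0.06 (adjusted p = 1.72e-07). DDIT4, a stress-induced inhibitor of mTOR signalling, fell from 83.6 to 15.4 (log2 fold change -2.36), DEPTOR, which binds mTOR, from 11.2 to 1.55 (-2.77), and SREBF1, a transcription factor of lipid synthesis at a locus overlapping RAI1, from 23.9 to 4.75 (-2.25). OLFML2A (-2.34), PBXIP1 (-2.43), TP53I11 (-2.21) and the aldolase gene ALDOC (-2.77, FPKM 7.98 to 1.09) fell by similar amounts. For each of these genes all 3 libraries of one group lay above all 3 of the other.

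The interferon response list had 20 of 24 tested members higher and none lower after overexpression, and 20 called when adjusted over the list alone. Its median log2 fold change was 2.78, and 1.66 with limma on the FPKM values (camera adjusted p = 1.52e-26, and adjusted p = 0.00185 with an estimated correlation). IFIT1 rose by 3.44, at a locus overlapping LIPA, and IFNB1, the gene of interferon beta, had no count in the controls and was at least 128-fold higher. All 10 tested NF-kappaB and cytokine genes rose, and 10 when adjusted over the list alone, with a median of 2.66 (adjusted p = 1.67e-13, and 0.00557 with an estimated correlation). They included TNFAIP3 (4.20) and NFKB2 (2.38). Of 15 immediate early genes 11 rose and none fell (12 called when adjusted over the list alone, median 2.57, adjusted p = 3.41e-24, and 0.00261 with an estimated correlation), JUN by 3.99.

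All 5 tested replication-dependent histone genes were higher after overexpression, 5 when adjusted over the list alone, with a median log2 fold change of 3.36 (adjusted p = 1.41e-06, and 0.0496 with an estimated correlation). H4C8 rose by 3.85 and H2AC8 by 3.36, in libraries made from poly(A) RNA, which most histone transcripts lack, and these genes have near-identical copies that share reads. Of 13 YAP and TEAD targets 10 rose and none fell, 10 when adjusted over the list alone (median 1.23, adjusted p = 1.39e-07, and 0.00557 with an estimated correlation), among them CCN2 (1.97) and AXL (0.97). The unfolded protein and integrated stress response list had 8 of 18 members higher and 3 lower, 11 when adjusted over the list alone (median 0.42, 0.26 after a median shift, adjusted p = 0.000268, and 0.0252 with an estimated correlation). PPP1R15A, which ends the block of translation in this response, rose by 3.74, and SESN2 by 2.03. The 4 study genes had a median of 0.60 (0.25 after a median shift) with 1 higher (NUSAP1 itself) and 1 lower (LDHA). Both were also called when adjusted over the list alone (2 genes, list adjusted p = 0.00034, and 0.0252 with an estimated correlation). The plasmid raised NUSAP1 itself, so this pass was partly fixed in advance, and the list was not tested without it. The call was lost without control 1 (adjusted p = 0.102), after quantile normalization (0.579), with limma on the FPKM values (0.561) or with the replicate number as a block (0.362). It was also lost without the 4 libraries with hepatocyte transcripts.

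Of 19 cholesterol synthesis genes 14 fell and 1 rose after overexpression, 15 when adjusted over the list alone. The median was -0.71 (adjusted p = 0.000268, and 0.0252 with an estimated correlation), with LSS at -1.45 and MSMO1 at -0.83. Of 23 glycolysis and lactate genes 16 fell and 2 rose, 18 when adjusted over the list alone (median -0.52, adjusted p = 0.000112, but adjusted p = 0.290 with an estimated correlation). They included ALDOC and PFKL (-1.23). The mitochondrially encoded list had 12 of 13 genes lower, 12 when adjusted over the list alone (median -0.65, adjusted p = 0.00446, but adjusted p = 0.623 with an estimated correlation), with MT-CO2 at -0.79, and after quantile normalization the median was -0.15 with 7 lower. Mitochondrial transcripts made up 11.7% ± 2.01 of the counts in control, 7.44% ± 0.648 in overexpression and 8.78% ± 0.814 in knockdown (SD, n = 3 each). Of 29 nuclear-encoded respiratory chain genes 15 fell and 2 rose, 17 when adjusted over the list alone (median -0.34, adjusted p = 0.0241, but adjusted p = 0.631 with an estimated correlation), with NDUFV1 at -0.99 and ATP5F1B at -0.57 (in TPM median -0.18, 7 lower and 2 higher). This call was lost without control 3 (adjusted p = 0.0624) or overexpression 2 (0.0556). Of 26 DNA replication genes 17 fell and none rose, 18 when adjusted over the list alone (median -0.32, adjusted p = 0.00662, but adjusted p = 0.326 with an estimated correlation), including PCNA (-0.72) and MCM6 (-0.55). In TPM their median was -0.16 with 7 lower and 1 higher. The cytosolic ribosomal protein list had 15 of 72 genes lower and 1 higher, 13 when adjusted over the list alone (median -0.18, adjusted p = 0.0241, but adjusted p = 0.692 with an estimated correlation). RPS3A was at -0.95 and RPS24 at -0.52. In TPM the median was -0.03 with 10 lower and 3 higher, after quantile normalization 26 were lower and 8 higher, and limma on the FPKM values gave 29 lower. The list no longer passed without control 3 (adjusted p = 0.112) or overexpression 2 (0.102), or after quantile normalization (0.0823) or with fry (0.120).

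The remaining 8 lists did not pass after overexpression. With fry 6 of them did, mitosis (adjusted p = 0.00237), mesenchymal and invasion (0.00266), epithelial (0.00891), hypoxia (0.0103), the tricarboxylic acid cycle (0.0249) and p53 targets (0.000164). Fry does not set a list against the other genes, and 53.4% of all tested genes changed here. These passes therefore do not show a larger change in these lists than in other genes. Fry placed the mesenchymal and invasion list higher, although its median was -0.28. Among mitosis genes, NUSAP1's own functional class, 10 of 30 were lower and 1 higher, 10 when adjusted over the list alone, with a median of -0.26 (adjusted p = 0.0551). The list passed without control 1 (adjusted p = 0.0424), overexpression 2 (0.0410) or overexpression 3 (0.0384), and after quantile normalization (0.00829), with limma on the FPKM values (0.00787) and with the replicate number as a block (0.0221). In TPM 2 were lower and 2 higher (median -0.13), and after a median shift 18 lower and none higher. KIF20A fell by 0.57 and CCNB2 fell by 0.49. Members of the mesenchymal and invasion list went both ways (6 of 15 higher, 7 lower, 13 when adjusted over the list alone, median -0.28, mean 0.29, adjusted p = 0.529). The integrin gene ITGA5 rose by 1.07. Of 12 epithelial genes 3 rose and 5 fell, 8 when adjusted over the list alone (median -0.10, and 0.05 in TPM, adjusted p = 0.541). CLDN1, a tight junction gene, rose by 2.23 and CDH1, the gene of E-cadherin, had a log2 fold change of -2.54. Hypoxia targets outside glycolysis had 6 of 16 higher and 7 lower, 14 when adjusted over the list alone (median -0.30, adjusted p = 0.367), with ANGPTL4 at 2.09. In the tricarboxylic acid cycle 5 of 14 fell and 1 rose, 3 when adjusted over the list alone (median -0.16, adjusted p = 0.303, but 0.0375 after quantile normalization and 0.0484 with limma on the FPKM values), and in TPM 2 fell and 2 rose (median -0.01). Of 17 p53 targets 5 rose and 3 fell, 8 when adjusted over the list alone (median 0.10, and -0.01 after a median shift, adjusted p = 0.367), with AEN at 2.58 and FDXR at -1.61. Heat shock genes had 3 of 10 higher and 4 lower, 7 when adjusted over the list alone (median -0.01, mean 0.04, median 0.15 in TPM, adjusted p = 0.819). Among markers of other cell types 16 of 20 were too low to test, and of the 4 tested CD68 (1.71) was higher and COL3A1 (-1.87) lower, 2 when adjusted over the list alone (median -0.30, adjusted p = 0.577).

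**Figure D2:**
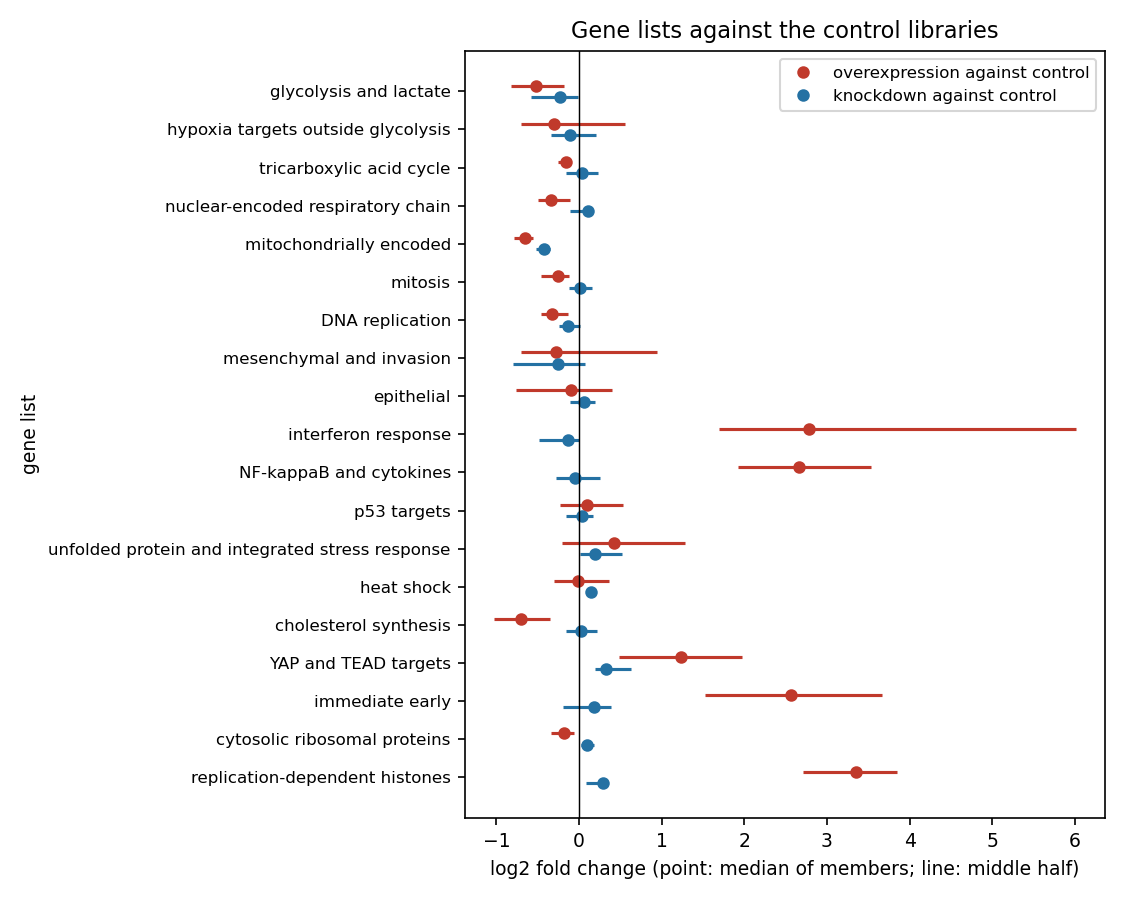
Median log2 fold change of the tested members of 19 gene lists (points) with their interquartile range (lines), for overexpression (red) and knockdown (blue) against the same controls. The interferon list lies at 2.78 after overexpression and at -0.14 after knockdown, and glycolysis lies below 0 in both.

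The comparison of knockdown with control asks what a loss of NUSAP1 transcript does to expression. After knockdown NUSAP1, LDHA, LDHB and genes such as CD24, OAT and GLO1 fell, while 6 of 13 YAP and TEAD targets and 5 of 18 genes of the unfolded protein and integrated stress response rose. These lists did not pass with an estimated correlation (adjusted p = 0.0641 and 0.0833). Mitosis genes as a list did not pass the test, with a median of 0.01. Of 12545 genes tested 1813 changed, 881 higher and 932 lower, and 247 changed at least 2-fold (90 higher and 157 lower). In TPM 1863 changed, 1414 higher and 449 lower. With the replicate number as a block the count was 2132 in the fit of all groups. In a fit of control and knockdown alone it was 1392 with the block and 1398 without it. DESeq2 called 2767 and the test without a filter on low values 1061.

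Among the largest decreases after knockdown, CD24, a cell surface glycoprotein, had a mean FPKM of 74.2 ± 1.15 in control and 21.2 ± 0.616 in knockdown (SD, n = 3 each), a log2 fold change of -1.82 ± 0.07 (SE, adjusted p = 1.45e-05). GLO1, the glyoxalase that detoxifies methylglyoxal formed in glycolysis, went from 83.4 ± 2.62 to 28.5 ± 0.997, a log2 fold change of -1.56 ± 0.06 (adjusted p = 1.45e-05). OAT, the ornithine aminotransferase, fell from 34.3 to 9.51 (log2 fold change -1.86), CACNG7 from 11.2 to 2.85 (-1.98), and the RNA-binding protein gene TAF15, at a locus overlapping AP2B1, from 41.1 to 12.4 (-1.74). Among the largest increases STK40, a protein kinase gene, went from 7.40 ± 2.94 to 24.0 ± 0.886 (log2 fold change 1.69 ± 0.27, adjusted p = 0.00575) and TMC7 from 2.09 ± 0.135 to 6.08 ± 0.520 (1.52 ± 0.09, adjusted p = 7.37e-05). MIEF1, a gene of mitochondrial fission, rose by 1.27. NBPF12 (1.81), NPIPB3 (1.54) and NBPF26 (1.45) also rose, but belong to families of near-identical genes that share reads. A search of annotated 3′ UTRs for heptamers that go with lower expression put AGTCTTC, GTCTTCA, TGTGGCT and GTGGCTA first, which form 2 overlapping pairs. Of 884 searched genes lower after knockdown 52.5% held at least 1 of the 4 leading heptamers, against 29.5% of 9751 other genes (Fisher's exact p = 3.91e-42), with the heptamers chosen on the same data. Of the genes named above, CD24, GLO1, OAT and CACNG7 fell and held at least 1 of them, and TAF15 fell and held none. NBPF12 and NBPF26 rose and held at least 1, and STK40, TMC7, MIEF1 and NPIPB3 rose and held none.

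The 4 study genes had 3 lower and none higher after knockdown, 3 when adjusted over the list alone (NUSAP1, LDHA and HIF1A, median -0.97, adjusted p = 3.01e-08, and 0.0178 with an estimated correlation). NUSAP1 is the target of the siRNA, so this pass was partly fixed in advance, and the list was not tested without it. Of 23 glycolysis and lactate genes 7 fell and none rose, 8 when adjusted over the list alone. Their median was -0.23, and -0.05 in TPM, with an adjusted p of 8.51e-05, but adjusted p = 0.399 with an estimated correlation. LDHB, the other main lactate dehydrogenase subunit, fell from an FPKM of 235 ± 7.92 to 98.7 ± 5.14 (log2 fold change -1.27 ± 0.12, adjusted p = 0.000536). Of the 7 genes lower, LDHA and PDK1 held at least 1 of the 4 heptamers and HK2, PFKL, PFKM, ALDOC and LDHB held none. The mitochondrially encoded list had 2 of 13 lower and none higher, 5 when adjusted over the list alone (median -0.42, adjusted p = 0.000524, but adjusted p = 0.626 with an estimated correlation). After quantile normalization the median was -0.06 with 0 lower (adjusted p = 0.445), and with fry the list did not pass (0.117). Of 26 DNA replication genes 3 fell and none rose, 3 when adjusted over the list alone (median -0.13, and 0.01 in TPM, adjusted p = 0.00537, but adjusted p = 0.399 with an estimated correlation). GINS1, of the replicative helicase, was at -1.42 and RRM2, of ribonucleotide reductase, at -0.76, and both held one of the heptamers.

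The YAP and TEAD targets had 6 of 13 higher and 1 lower after knockdown, 9 when adjusted over the list alone (median 0.33, adjusted p = 0.000524, but adjusted p = 0.0641 with an estimated correlation), with AJUBA at 0.72 and CCN2 at 0.58. The unfolded protein and integrated stress response list had 5 of 18 higher and none lower, 5 when adjusted over the list alone (median 0.20, 0.32 in TPM, adjusted p = 0.00245, but adjusted p = 0.0833 with an estimated correlation). PPP1R15A rose by 0.96 and SESN2 by 0.92.

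The other 15 lists did not pass after knockdown. With fry, which does not set a list against the other genes, the hypoxia (adjusted p = 0.0236), mesenchymal and invasion (0.00797) and heat shock lists (0.0115) did. No mitosis gene was higher and 1 of 30 was lower, 0 when adjusted over the list alone, with a median of 0.01, a mean of -0.00 and a median of -0.03 after quantile normalization (adjusted p = 0.836). In TPM 4 were higher (median 0.14), and after quantile normalization 5 were higher and 2 lower. In the interferon list 3 of 24 fell and none rose, 3 when adjusted over the list alone (median -0.14, adjusted p = 0.226), and the list passed without control 1 (adjusted p = 0.0128). Of 10 NF-kappaB and cytokine genes 1 rose, 2 when adjusted over the list alone (median -0.05, and 0.08 in TPM, adjusted p = 0.960). Immediate early genes had 4 of 15 higher and 1 lower, 6 when adjusted over the list alone (median 0.18, and 0.03 after quantile normalization, adjusted p = 0.257), with EGR1 at 0.76. Hypoxia targets had 3 of 16 lower, 7 when adjusted over the list alone (median -0.11, and 0.02 in TPM, adjusted p = 0.197), and P4HA2, a collagen prolyl hydroxylase gene with one of the heptamers, was at -1.54. Mesenchymal and invasion genes had 2 of 15 higher and 6 lower, 9 when adjusted over the list alone (median -0.26, adjusted p = 0.124), with ITGA5 at 0.82. At least 1 of the 4 heptamers was held by 1 of 3 lower hypoxia targets, which was P4HA2. It was so for 1 of 3 lower interferon genes and 1 of 6 lower mesenchymal and invasion genes. Of all 10635 searched genes 31.4% held at least 1. Cytosolic ribosomal proteins had 2 of 72 higher and none lower, 0 when adjusted over the list alone (median 0.10, adjusted p = 0.124), and passed without control 3 (adjusted p = 0.00426) or knockdown 2 (0.000705), and after quantile normalization (0.0146), with limma on the FPKM values (0.0360) and without the 4 libraries with hepatocyte transcripts (0.0404). In TPM 7 were higher (median 0.24).

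Of the remaining lists after knockdown, the nuclear-encoded respiratory chain had 2 of 29 higher and 1 lower, 3 when adjusted over the list alone (median 0.11, adjusted p = 0.587), with SDHD at 0.50. The tricarboxylic acid cycle had 1 of 14 higher and 2 lower, 8 when adjusted over the list alone (median 0.04, adjusted p = 0.836), but 6 higher and none lower in TPM (median 0.18) and 4 higher and 2 lower with limma on the FPKM values. Among p53 targets 1 of 17 rose and 2 fell, 3 when adjusted over the list alone (median 0.04, adjusted p = 0.836), with XPC, a DNA repair gene, at -0.63. In cholesterol synthesis 1 of 19 rose and 1 fell, 4 when adjusted over the list alone (median 0.03, mean -0.01, adjusted p = 0.836), with MVD at -0.68. XPC and MVD each held at least 1 of the 4 heptamers, and FDXR, the other lower p53 target, held none. Epithelial genes had 1 of 12 lower, 1 when adjusted over the list alone (median 0.06, mean -0.02, adjusted p = 0.950). Heat shock genes had 1 of 10 higher, 0 when adjusted over the list alone (median 0.14, adjusted p = 0.202), and histone genes 1 of 5 higher, 1 when adjusted over the list alone (median 0.29, and 0.06 with limma on the FPKM values, adjusted p = 0.617). In TPM 4 heat shock genes were higher (median 0.27), 4 of cholesterol synthesis (0.16) and 3 of the nuclear-encoded respiratory chain (0.25). Of the 4 tested markers of other cell types, LYZ and ALB were lower, 4 when adjusted over the list alone (median -3.98, -3.96 with LYZ at its bound and -0.69 with limma on the FPKM values, adjusted p = 0.587). LYZ, the lysozyme gene, had no count in the knockdown libraries and was at least 310-fold lower.

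ALB, the albumin gene of hepatocytes, had 16, 1087 and 1131 counts in the control libraries, 918, 11 and 950 in overexpression, and 4, 0 and 3 in knockdown. A list of 18 transcripts abundant in hepatocytes, written after the counts were seen, summed to 77.5 and 99.97 CPM (counts scaled to the library total) in control 2 and 3 and to 71.8 and 84.1 in overexpression 1 and 3. It summed to 3.60 in control 1, 2.36 in overexpression 2, and 1.36, 0.890 and 1.69 in the knockdown libraries. These transcripts were thus high in 2 of 3 libraries of each of the other groups and in no knockdown library. Without those 4 libraries, which leaves 1 control and 1 overexpression library, 2419 genes changed after overexpression and 6 after knockdown. NUSAP1 was then at -1.38 after knockdown (adjusted p = 0.0842) and LDHA at -1.21 (adjusted p = 0.109). Leaving out a single library gave 1116, 1174 and 1060 changed genes without control 1, 2 and 3 and 962 without knockdown 1.

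**Figure D3:**
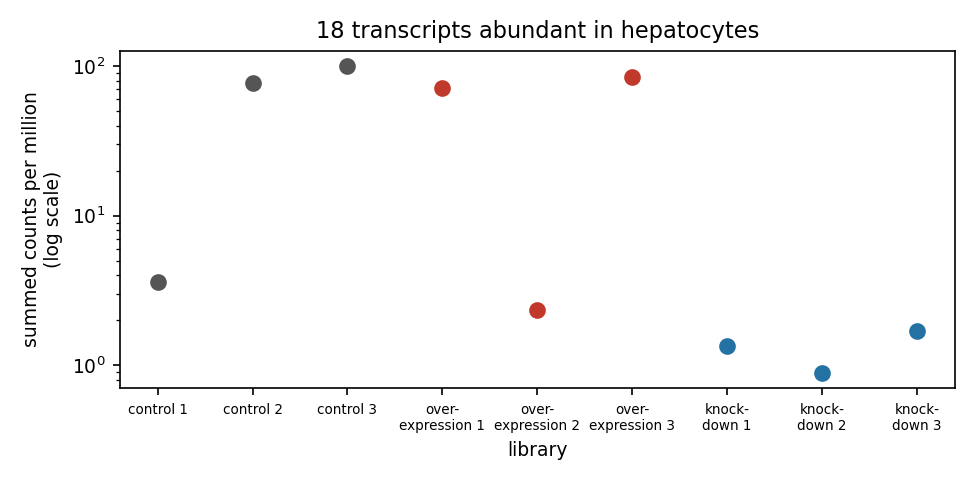
Summed CPM (counts scaled to the library total, log scale) of 18 transcripts abundant in hepatocytes in each of the 9 libraries. Control 2 and 3 and overexpression 1 and 3 lie between 71.8 and 99.97, and the other 5 libraries between 0.890 and 3.60.

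The direct comparison of overexpression with knockdown takes no difference from the control libraries, which enter only the filter, the scaling factors and the shared estimate of the spread. A fit of the 6 libraries alone called 5915 genes. NUSAP1 was higher in overexpression by 10.16 ± 0.15 on the log2 scale (adjusted p = 1.1e-08), and LDHA by 0.38 ± 0.10 (adjusted p = 0.0123). HIF1A was higher by 0.78 ± 0.15 (adjusted p = 0.00258), and MYC had a log2 fold change of 1.69 ± 0.88 (adjusted p = 0.146). Of 12545 genes 6270 differed, 3193 higher and 3077 lower in overexpression (2692 and 3819 after a median shift), and 1903 differed at least 2-fold, and 4069 differed with a filter of FPKM 5. IFIT2 was higher by 7.78, CCL5 by 5.98 and EGR1 by 5.45, and IFNL1, with no count in knockdown, was at least 1146-fold higher. DEPTOR (-2.52), PLCXD1 (-2.43), PBXIP1 (-2.34), MKNK2 (-2.08) and VWA1 (-1.85) were lower. The difference in LDHA did not pass without the filter on low values (adjusted p = 0.0565) or after a median shift of the FPKM values (0.0601), or without the 4 libraries with hepatocyte transcripts (0.261).

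Of the 21 lists 12 passed between overexpression and knockdown. The interferon list was higher in overexpression with 21 of 24 genes (22 when adjusted over the list alone, median 2.96, and 1.68 after a median shift, adjusted p = 1.42e-33), NF-kappaB and cytokines with 10 of 10 (10, median 2.91, adjusted p = 2.22e-15) and immediate early genes with 11 of 15 (11, median 2.39, adjusted p = 2.21e-25). Each of these 3 had an adjusted p of 0.00225 with an estimated correlation. Histone genes were higher with 5 of 5 (5 when adjusted over the list alone, median 3.27, adjusted p = 9.33e-07, and 0.0204 with an estimated correlation) and YAP and TEAD targets with 9 of 13 (9, median 0.91, adjusted p = 7.06e-05, and 0.0162 with an estimated correlation). Of the 4 study genes 3 were higher (3 when adjusted over the list alone, median 1.23, adjusted p = 3.13e-09, and 0.00395 with an estimated correlation). They include NUSAP1, which the plasmid raised and the siRNA lowered, so this pass was partly fixed in advance. Cholesterol synthesis was lower in overexpression with 13 of 19 genes and higher with 1 (14 when adjusted over the list alone, median -0.73, adjusted p = 4.83e-05, and 0.0162 with an estimated correlation).

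The other 5 passing lists were lost with an estimated correlation. Glycolysis had 12 of 23 lower and 5 higher, 18 when adjusted over the list alone (median -0.34, adjusted p = 0.0416, but adjusted p = 0.642 with an estimated correlation), and did not pass without overexpression 2 (adjusted p = 0.0949) or knockdown 3 (0.0712), or after quantile normalization (0.147), with limma on the FPKM values (0.0895) or with the block (0.0518). The nuclear-encoded respiratory chain had 13 of 29 lower, 13 when adjusted over the list alone (median -0.35, adjusted p = 0.00532, but adjusted p = 0.642 with an estimated correlation). Mitosis had 12 of 30 lower, 11 when adjusted over the list alone (median -0.29, adjusted p = 0.0324, but adjusted p = 0.291 with an estimated correlation), and did not pass without overexpression 1 (adjusted p = 0.0959) or knockdown 2 (0.0508), or without the 4 libraries with hepatocyte transcripts (0.0817). Cytosolic ribosomal proteins had 30 of 72 lower, 28 when adjusted over the list alone (median -0.26, adjusted p = 0.000852, but adjusted p = 0.642 with an estimated correlation). The unfolded protein and integrated stress response had 7 of 18 higher and 4 lower, 13 when adjusted over the list alone (median 0.38, 0.23 after a median shift, adjusted p = 0.0134, but adjusted p = 0.0889 with an estimated correlation), and did not pass without knockdown 2 (adjusted p = 0.0529) or knockdown 3 (0.0540), or after quantile normalization (0.0943), with limma on the FPKM values (0.0992), with the block (0.0978) or without the 4 libraries with hepatocyte transcripts (0.0855). The remaining 9 lists, among them the mitochondrially encoded genes (1 of 13 lower, adjusted p = 0.224, but 0.0302 after quantile normalization) and the mesenchymal and invasion genes (7 of 15 higher and 3 lower, adjusted p = 0.12), did not pass. Of these DNA replication passed after quantile normalization (0.0291), with limma on the FPKM values (0.0306) and with fry (0.0102), and the tricarboxylic acid cycle after quantile normalization (0.0459) and with fry (0.0163). The mesenchymal and invasion (6.08e-05), p53 (6e-05) and epithelial lists (0.0120) also passed with fry. As fry does not set a list against the other genes, its passes do not show a larger change in these lists than in other genes.

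If expression followed the amount of NUSAP1, genes would move in opposite directions in the comparisons against control. Of 1295 genes that changed in both, 1059 moved in the same direction (559 higher and 500 lower in both) and 236 in opposite directions, where independent lists would give 483.9 and 484.6. Leaving out control 1, 2 or 3 or knockdown 1 gave 113, 123, 130 or 125 genes in opposite directions and 649, 717, 609 or 584 in the same direction. The test without a filter gave 113 and 608, DESeq2 402 and 1607, and the fit without the 4 libraries with hepatocyte transcripts 0 and 5. Among genes that moved the same way, ANKRD1 rose by 6.88 after overexpression and 2.85 after knockdown, DUSP8, a MAP kinase phosphatase gene, by 5.59 and 1.73, DUSP16 by 2.52 and 1.55, and TMC7 by 2.06 and 1.52. STK40 rose by 1.73 and 1.69, and CD24 had log2 fold changes of -2.02 and -1.82. Of the glycolysis list 7 genes changed in both, 6 of them lower in both (PFKL, PFKM, ALDOC, LDHA, LDHB and PDK1), and HK2 went in opposite directions. Besides NUSAP1, genes in opposite directions included NCEH1, a cholesteryl ester hydrolase gene with heptamers of both pairs in its 3′ UTR, at 1.32 ± 0.06 and -1.30 ± 0.06 (adjusted p = 1.79e-06 and 4.49e-05). MKNK2, a kinase gene of translational control that also holds one of the heptamers, was at -1.11 ± 0.17 and 0.97 ± 0.17 (adjusted p = 0.000791 and 0.00883). Across genes, which are not independent replicates, the correlation of the log2 fold changes was 0.40 (Pearson and Spearman) and their covariance 0.225. In 20 simulations of unchanged groups against the same controls the correlation averaged 0.501 and the covariance 0.0589, with 0.1 genes called in the same direction. No gene was changed there and libraries were not paired. That count therefore cannot show how far shared controls tip genes called in both comparisons.

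**Figure D4:**
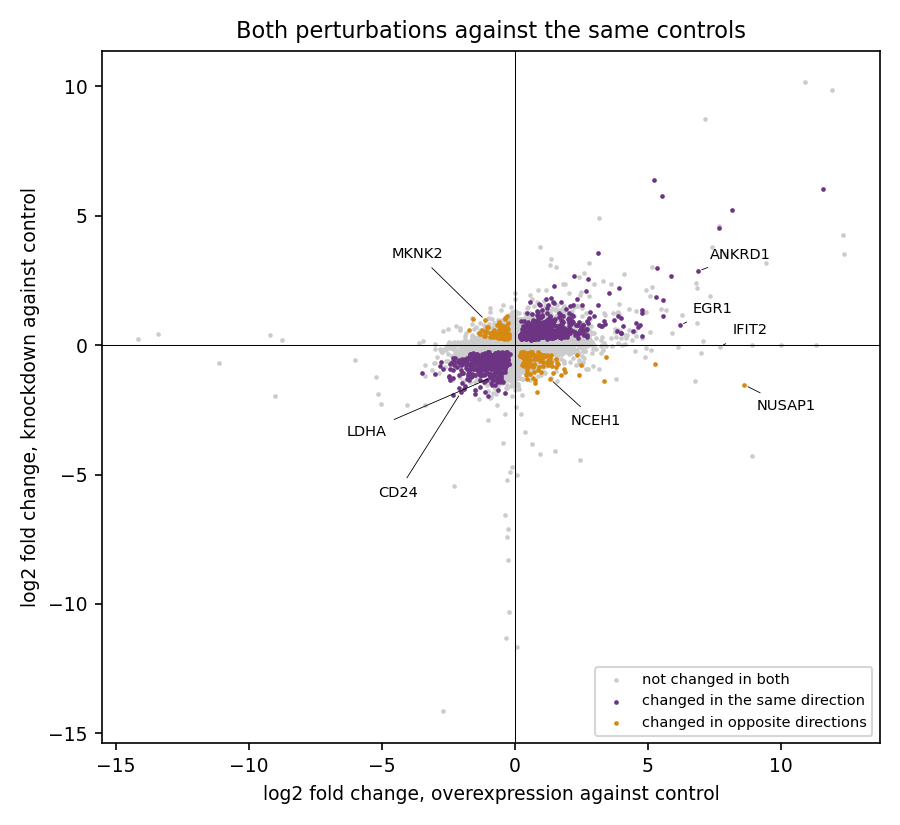
Log2 fold change after knockdown against that after overexpression for each tested gene (points), with the 1059 genes that changed in the same direction in purple and the 236 in opposite directions in orange. NUSAP1 lies at 8.63 and -1.53, and LDHA and CD24 are lower in both.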

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

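In this part the tests of interferon, cytokine and immediate early genes against transfection and plasmid DNA, and those of the amount of NUSAP1 and of transfection common to both perturbations, and the splits by numbered pairs, were chosen only after the result was seen.

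The effects of overexpression and knockdown against the same controls differed when the difference itself was tested. NUSAP1 differed by 10.16 on the log2 scale (edgeR adjusted p = 1.1e-08), LDHA by 0.38 (0.0123, but 0.0565 without a filter, 0.0601 after a median shift and 0.261 without the 4 libraries with hepatocyte transcripts) and HIF1A by 0.78 (0.00258). The study genes differed by a median of 1.23 (camera adjusted p = 0.00395 with an estimated correlation, as for the other lists here). They include NUSAP1, which the plasmid raised and the siRNA lowered, so this difference was partly fixed in advance. The interferon list differed by 2.96 (0.00225), NF-kappaB and cytokines by 2.91 (0.00225), immediate early genes by 2.39 (0.00225) and histones by 3.27 (0.0204). The YAP and TEAD targets differed by 0.91 (0.0162) and cholesterol synthesis by -0.73 (0.0162).

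Interferon, cytokine and immediate early genes were higher after overexpression. If transfection of any nucleic acid raised them alike, they would rise about as much after knockdown. The interferon list was higher in overexpression than in knockdown by a median of 2.96, cytokines by 2.91 and immediate early genes by 2.39. This argues against such an equal effect as the whole cause, but whether a plasmid and an siRNA act alike was not tested. Immediate early genes had a median of 0.18 after knockdown with 4 of 15 higher and 1 lower. As a list they did not pass there (camera adjusted p = 0.257, and 0.632 with an estimated correlation). Whether transfection accounts for a small part of their rise therefore stays open. An earlier bound on the number of higher members had left them undecided. Plasmid DNA in the cells and the excess of NUSAP1 itself cannot be told apart, since 0 libraries had a plasmid lacking NUSAP1. A response to plasmid DNA may therefore account for some of these genes, as a hypothesis that a library with an empty plasmid would test.

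Most genes that changed in both comparisons moved in the same direction, with lower glycolysis genes in both. As a list, glycolysis did not pass with an estimated correlation after overexpression or knockdown (camera adjusted p = 0.290 and 0.399). Shared control libraries push both fold changes the same way. The covariance of 0.225 was above the highest of 20 simulations in which no gene changed (0.0855), which argues against them as the whole cause. It was lower in genes with a searched 3′ UTR, 0.154 with a leading heptamer and 0.157 without, for which no simulation was run. The Pearson correlation of 0.40 lay below the lowest simulated one (0.425), so it does not argue the same way. Among genes whose 3′ UTR holds no hexamer of the leading heptamers 433 moved the same way and 95 apart. If the amount of NUSAP1 set the glycolysis genes they would move apart, yet of 7 called in both, 6 members moved the same way, and HK2 did not, too few to decide. Transfection common to both perturbations stays open, since 0 control libraries are labelled as transfected, and is a candidate explanation for the shared direction.

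Genes lower after knockdown shared sequences in their 3′ UTRs. The heptamer AGTCTTC had the lowest z, -13.6 (-0.75 after overexpression), against -5.16 as the lowest in shuffled data, and all 9 of 15360 heptamers that passed share 5 bases with it or with TGTGGCT, which suggests an off-target effect through the seed of the siRNA. TGTGGCT and the reverse complement of AGTCTTC lie in one 19-base stretch of NUSAP1 (GGAAGACTCTCTGTGGCTT, chromosome 15, 41365450 to 41365468 on GRCh38, coding), held by 6 of 6 NUSAP1 transcripts, as both strands of 1 siRNA against NUSAP1 would need. With either heptamer as the reverse-complemented one, 5 of 19666 genes, NUSAP1 included, held such a stretch. LDHA has 3 positions of the leading heptamers in its annotated 3′ UTRs, 1 pair of them overlapping. Its fall after knockdown may therefore not come from NUSAP1, although the fall after overexpression is not addressed by this. Such heptamers are common, held by 31.4% of 10635 searched genes, and 464 of 3336 holders were lower after knockdown. Genes with AGTCTTC followed by A, as in LDHA, had a median log2 fold change of -0.17, against -1.24 for LDHA. LDHB fell after knockdown and held none. The sequence of the siRNA is not given in the sources used here, so the off-target effect is a hypothesis. It rests on a rule for choosing transcripts that was changed after a first result (z -13.5 with 8 heptamers passing, and 0 rather than 2 passing after overexpression).

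Splits of the same libraries into other groups of 3 were compared with the real groups. For each comparison the 10 splits are too few for a share under 0.05. The real split of overexpression and control gave 6702 genes and the highest other 1, for knockdown and control 1813 and 1, and for overexpression and knockdown 6270 and 1, so that 1 of 10 splits gave as many each time. For lists the real and highest other counts were 13 and 12 (1 split as large), 6 and 6 (2 splits), and 12 and 10 (1 split). Of the 10 splits of control and knockdown, 4 part all 3 numbered pairs as the real one does, and the highest of the other 3 gave 1 gene and 4 lists, while a split that parts fewer pairs gave 6 lists. For the 236 genes in opposite directions, 1 of 100 splits of the 9 libraries, the real one, gave as many, and the highest other gave 1. Nearly every other split mixes libraries of different real groups, which raises the spread within groups and lets few genes be called. These splits also do not keep the pairing of control and knockdown by number, so they cannot decide whether the 236 arose by chance.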

How the results depend on the processing

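The tests with DESeq2, RLE factors, library totals, the planned limma fit, a fit without NUSAP1, the fit of 2 groups with a block and the fit without 4 libraries were chosen only after the result was seen. No named gene or list that passed in a test turned to the opposite direction past the threshold, but the balance of all calls did turn with the scaling. After overexpression 3438 higher and 3264 lower genes became 2924 and 3928 after a median shift, and after knockdown 881 and 932 became 1414 and 449 in TPM. The DNA replication list was lower after knockdown, but did not pass with an estimated correlation (camera adjusted p = 0.399). In TPM, where it was not tested, its median was 0.01. NUSAP1 kept a log2 fold change of 8.50 to 8.82 after overexpression and -1.63 to -1.36 after knockdown, and LDHA -0.95 to -0.70 and -1.37 to -1.10, all past the threshold except as given here. For named genes, 2090 of the values under other settings stayed on their side of the threshold, 164 lost the call and 8 gained one, and with single libraries left out 795 stayed and 87 lost it. For lists these were 377, 34 and 30, and with single libraries left out 361, 11 and 6.

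With no filter on low values 1061 genes changed after knockdown, 113 went in opposite directions, and LDHA differed between overexpression and knockdown by 0.35 without passing (adjusted p = 0.0565). More genes were tested there. After a median shift that difference was 0.27 (0.0601), and the cause was not tested. With a filter of FPKM 5, which tests fewer genes, 4229 changed after overexpression and 4069 differed between overexpression and knockdown. DESeq2 called 2767 after knockdown (1812 shared) and 402 in opposite directions (236 shared), and the cause was not tested. A 2-fold minimum left 2233, 247, 1903 and 8. An estimated correlation left 8, 1 and 7 lists, and the 1 after knockdown was the study genes, which include NUSAP1 itself. It left 0 GO terms in each comparison (112, 31 and 104 with camera at an unadjusted p under 0.05), and 0, 0 and 6 KEGG terms (49, 7 and 45 unadjusted), and the cause was not tested.

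Leaving out the 4 libraries with hepatocyte transcripts, which leaves control and overexpression with 1 library each that is assumed to vary like the others, gave 2419 genes after overexpression (2271 shared), 6 after knockdown (2 shared), 3539 between overexpression and knockdown and 0 in opposite directions. NUSAP1 after knockdown was then at -1.38 (adjusted p = 0.0842), LDHA at -1.21 (0.109), and LDHA between overexpression and knockdown at 0.28 (0.261). This fit has fewer libraries. Leaving out single libraries gave 962 to 1410 genes after knockdown (962 without knockdown 1, 1060 without control 3), 5851 to 6296 after overexpression, 5354 to 6004 between overexpression and knockdown, and 113 to 217 in opposite directions.

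With the replicate number as a block, which the numbers support only for knockdown and control, 2132 genes changed after knockdown, 7068 after overexpression, 6643 differed between overexpression and knockdown and 309 went in opposite directions. In a fit of control and knockdown alone 1392 genes changed with the block and 1398 without it. With the block NUSAP1 was there at -1.53 (edgeR adjusted p = 0.0166) and LDHA at -1.26 (0.0157). At the depth and spread of these libraries edgeR found 4.48% and DESeq2 34.3% of simulated 1.5-fold changes after knockdown, with 6 and 41 false calls, and depth itself was not varied. The simulation changed far fewer genes than were called here, so these shares may not hold for the real calls.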

Other observations

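The tests of GO and KEGG terms were planned, and the list of hepatocyte transcripts was the only one here chosen only after the result was seen. Genes of ribosome biogenesis were higher after overexpression, with 66 of 91 tested genes of this GO term higher and 4 lower (camera adjusted p = 4.36e-09, but adjusted p = 0.104 with an estimated correlation). Of 152 genes of rRNA processing 92 were higher and 9 lower (adjusted p = 6.16e-06, but adjusted p = 0.492 with an estimated correlation). The cytosolic ribosomal proteins themselves had a median log2 fold change of -0.18. Genes of the extracellular matrix were lower, with 58 of 93 genes of the term collagen-containing extracellular matrix lower and 5 higher (adjusted p = 1.48e-07, but adjusted p = 0.360 with an estimated correlation), and 25 of 31 structural constituents of the matrix lower and 1 higher (adjusted p = 1.55e-05, but adjusted p = 0.287 with an estimated correlation). The nucleosome term had 37 of 50 genes higher and 5 lower (adjusted p = 8.97e-07, but adjusted p = 0.360 with an estimated correlation). In KEGG, circadian rhythm had 15 of 25 genes higher and 1 lower (adjusted p = 6.32e-06, but adjusted p = 0.160 with an estimated correlation).

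After knockdown the GO term pyruvate metabolic process had 6 of 19 genes lower and none higher (adjusted p = 2.25e-06, but adjusted p = 0.999 with an estimated correlation). Between overexpression and knockdown 6 KEGG terms passed with an estimated correlation too. TNF signaling had 42 of 73 genes higher in overexpression and 9 lower (adjusted p = 0.0366 with an estimated correlation), RIG-I-like receptor signaling 25 of 44 higher and 5 lower (0.0397), and ribosome biogenesis 41 of 73 higher and 1 lower (0.0397). NF-kappa B signaling, IL-17 signaling and osteoclast differentiation also passed (0.0397 each).

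The hepatocyte transcripts varied together between libraries of the same group. Of 18, 15 were higher in each of control 2, control 3, overexpression 1 and overexpression 3 than in any other library. LYZ had 231, 296 and 426 counts in control, 332, 12 and 388 in overexpression and 0 in each knockdown library.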
